A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

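9 libraries of polyA RNA from Saccharomyces cerevisiae were analysed, 3 from each of 3 strains. Per the labels' protocols, shake-flask cultures were grown at 30 °C in synthetic medium with 20 g/l glucose to an optical density of 12.5 at 660 nm. About 240 mg of wet biomass was quenched in liquid nitrogen, and libraries were made with the TruSeq RNA V2 kit and sequenced on an Illumina HiSeq instrument. The groups and replicate numbers were taken from the sample titles. The labels do not say that the 3 libraries of a strain came from separate cultures, so p-values measure the spread between these samples, which may be technical.

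The authors deposited whole-number counts per library, not normalised, for 6647 marker rows, each a gene name with a position in the gene, and for 3 rows that name no gene. Those 3 rows hold reads with several targets, unmapped reads and reads of low quality. They were left out of library sizes and tests; unmapped reads were 14.2% to 20.0% of a library's counts, reads with several targets 3.89% to 6.03% and reads of low quality 2.04% to 2.45%. The aligner, the counting program, the genome build, and how a read that covers several markers was counted are not given in the sources used here. The kit as labelled does not mark strand and no strand setting is given, so genes that overlap or lie antisense to another cannot be told apart from it. Counts of near-identical genes (ribosomal protein pairs, HXT, COS and PAU families, IMD, SSB, deleted glycolytic paralogs) are uncertain in the same way, because the counting rule for shared reads is not given.

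Outside the relocated glycolytic genes the files held 5429 genes, 5084 of them with 1 marker and 345 with 2 or more, up to 27. Of 5041 genes with 1 marker and a reference length, 4500 had it 10 bases before the end of the gene. Markers of a gene were added together. Systematic names were matched to the yeast reference table R64 for 5371 genes; that table was used only for names, gene length and GC content, and no coordinates are given. The 13 relocated genes had 59 marker rows for their native and watermarked copies. For 12 of them every row was listed at 0 in all 9 libraries, a value that cannot be read as absence of expression; only ENO2 had counts. Tests planned on the 13 relocated genes therefore ran on 1 gene, and the comparison of both copies inside the double libraries, planned as an edgeR fit over 13 genes, was fitted on ENO2 alone and is reported with an exact sign-flip test.

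Marker counts per library were 16982643 to 20110100. Intervals for shares are exact binomial 95% intervals and cover counting error only. Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, glmQLFit and glmQLFTest, all 9 libraries in a fit with strain as the only term, Benjamini-Hochberg adjustment, threshold 0.05); 5369 genes were tested in each comparison. Fold changes are edgeR log2 values with SE. CPM values (counts relative to library size) were scaled with the TMM factors, with a prior count of 2 on the log2 scale. Values by copy and by marker, and per-library measures, were compared with two-sided exact permutation tests, for which 3 libraries against 3 allow no p below 0.1.

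Before the data were examined, 40 gene lists were fixed: relocated glycolytic genes, deleted minor paralogs, loci and marker genes of the construction, glycolytic regulators, trehalose and glycogen, pentose phosphate pathway, glycerol metabolism, hexose transport and sensing, TCA cycle, gluconeogenesis with glyoxylate and alternative carbon, respiratory chain and ATP synthase, mitochondrially encoded genes, ethanol with acetaldehyde and acetate, thiamine, histidine, branched-chain, pyrimidine, arginine and lysine synthesis, sulfur and methionine, the phosphate, iron and zinc regulons, nitrogen catabolite genes, ergosterol, fatty acid and phospholipid, heat shock, general, oxidative and ER stress, ribosome biogenesis, cytosolic ribosomal proteins, MATa-specific, MATalpha-specific, haploid and mating, sporulation, cell wall integrity, galactose and maltose, both cell cycle lists, and subtelomeric genes. Lists with at least 3 tested members (38 of 40) were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and adjusted over the lists; camera with an estimated correlation and fry were run as second tests. Called members were counted with p adjusted over all genes and over the list alone.

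The rule for named genes, also fixed then, took the relocated genes, the deleted paralogs, loci and markers, the 12 largest changes per comparison (adjusted p under 0.05, mean log2 CPM of at least 2, no overlap of the libraries of the groups), and the called members with the smallest p of each list, up to 3. Other list members are named where a count was 5 or fewer; those were chosen after their values were seen.

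The fits were tested on simulated counts with 200 genes changed by known folds. At 1.5-fold, 91.0% of 67 genes were recovered in watermarked vs native, 94.0% in double vs native and 92.5% in double vs watermarked; at 2-fold and 4-fold 100% were recovered in each. False calls numbered 9, 11 and 16. In the test of the lists, a shifted list was called in each comparison and 0 of the other lists were. The simulated genes were drawn independently, whereas the estimated correlation was 0.67 for ribosomal protein and 0.73 for ribosome biogenesis genes. The simulation therefore cannot show how often correlated genes give false calls of lists. It also changed only 200 genes, whereas 59.8% of tested genes were called in double vs native and 60.1% in double vs watermarked. Recovery and false calls are therefore not shown for differences that broad.

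Alternatives tried were RLE factors, TMM factors without the relocated genes, total counts, no filter or a CPM filter, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, limma-voom and fits of 2 groups. Added after the data were seen were the marker nearest the 3' end only, removal of trends with gene length or GC content (values for 98.9% of 5442 genes), a 3' end index as covariate, and leaving out native 1 and double 3 together. That index is the median log2 ratio, over 180 genes with markers at least 200 bases apart and 100 counts, of counts at the marker nearest the 3' end to counts at the most upstream marker, relative to the mean of all libraries.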

Results

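RNA of 3 yeast strains was counted to compare expression of native gene copies with that of watermarked copies, which carry changed bases so that reads of near-identical genes can be told apart. Per the labels, the native strain carried its set of glycolytic genes at the CAN1 locus, and the watermarked strain carried a watermarked set at the same locus. The double strain carried the native set at CAN1 and the watermarked set at SGA1. The labels of the native and watermarked strains also list removal of the glycolytic genes from their original places, a Cas9 gene at PFK2, and the Kluyveromyces URA3 gene (KlURA3) at SGA1; the label of the double strain lists none of these. Each strain had 3 libraries. Their marker counts ran from 17870664 to 19651225 in native, from 19058373 to 20110100 in watermarked and from 16982643 to 19277637 in double libraries.

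The double libraries stood apart in the shares of unmapped reads and of reads with several targets. Unmapped reads made up 19.2% ± 0.620 (SD, n = 3) of their counts, against 15.3% ± 0.150 in native and 14.5% ± 0.314 in watermarked libraries. Reads with several targets were 3.98% ± 0.0856, 5.59% ± 0.0891 and 5.95% ± 0.146 in the same order. The exact permutation test gave p = 0.1 for each pair of strains, the smallest value 3 against 3 libraries allow. Which genes these reads came from is not known. Reads of the 12 relocated genes listed at 0 may be among them, so these shares need not be independent of the glycolytic sets. Coverage toward the 3' end of genes, as the log2 index relative to all libraries, was 0.67 in native 1 against 0.07 in native 2 and 0.03 in native 3. It was between -0.15 and 0.01 in watermarked libraries and -0.06, -0.22 and -0.39 in double 1, 2 and 3. Of 3 double libraries, double 3 differed most from the others, with a chi-square per degree of freedom of 56.7 and 50.3 against 12.3 between double 1 and double 2.

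Genes that the labels list as deleted were near the floor. The 12 deleted minor glycolytic paralogs found in the files together took 0.00372% to 0.00436% of marker counts in native and watermarked libraries and 0.00880% to 0.0104% in double libraries. ENO1, the minor enolase, had 12.7 ± 1.82 CPM (counts relative to library size, SD, n = 3) in native, 11.6 ± 0.763 in watermarked and 25.3 ± 4.92 in double libraries. TDH2, a glyceraldehyde-3-phosphate dehydrogenase, had 8.61 ± 0.515, 8.47 ± 0.986 and 18.1 ± 0.234 CPM, and PDC5, a pyruvate decarboxylase, 5.80 ± 0.202, 8.76 ± 1.52 and 19.3 ± 3.45 CPM. These genes are near-identical to relocated ones, so a share of such counts can belong to those. CAN1, the arginine permease, had 97.7 ± 1.15, 89.7 ± 1.01 and 80.5 ± 14.9 CPM, and SGA1, the sporulation glucoamylase, 6.31 ± 1.22, 5.17 ± 0.473 and 7.00 ± 1.66 CPM. Their single markers lie near the 3' end and may fall outside the replaced part, so these values check nothing.

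ENO2, the main enolase of glycolysis (YHR174W), was the 1 relocated gene with counts. Its 2 copies gave almost equal counts inside the double libraries: the log2 ratio of watermarked to native was 0.09 ± 0.07 (SD, n = 3), a ratio of 1.06, positive in all 3 libraries. The two-sided exact sign-flip test gave p = 0.25, the smallest value that 3 libraries allow. The copies lay at different loci, so sequence and locus cannot be told apart in this ratio. By marker pair the log2 ratio was 0.15 ± 0.06 at the 3' end, 0.24 ± 0.09 at the first middle pair and -0.17 ± 0.05 at the second (SD, n = 3). Less the log2 ratio of the watermarked strain to the native strain, the ratio of the sums was -0.02 ± 0.12 (SE), and by marker pair 0.24 ± 0.14, -0.22 ± 0.13 and -0.18 ± 0.13. In strains that lack a copy, the absent copy took 0.144% ± 0.0211 (SD, n = 3) of the ENO2 counts in native and 0.0553% ± 0.0150 in watermarked libraries. By library these shares ran from 0.126% (exact binomial 95% interval 0.108% to 0.147%) to 0.167% (0.144% to 0.193%) in native libraries. In watermarked libraries they ran from 0.0422% (0.0323% to 0.0543%) to 0.0717% (0.0584% to 0.0870%).

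Both copies of ENO2 together came to 12514 ± 837 CPM (SD, n = 3) in double, 7036 ± 831 in native and 7551 ± 469 in watermarked libraries. By edgeR, ENO2 rose by 0.83 ± 0.09 on the log2 scale in double vs native (SE; adjusted p = 3.09e-05) and by 0.73 ± 0.09 in double vs watermarked (adjusted p = 7.24e-05). With the trend with GC content removed these were 0.55 (adjusted p = 0.000303) and 0.44 (adjusted p = 0.00144), and at the marker nearest the 3' end 0.41 (adjusted p = 0.0118) and 0.51 (adjusted p = 0.00357). Watermarked vs native gave 0.10, with an adjusted p of 0.605, and adjusted over the list alone the relocated genes gave 1 call in double vs native, 1 in double vs watermarked and 0 in watermarked vs native. The fold of double over native depended on the marker, 1.32 at the 3' end and 2.33 and 2.05 at the middle markers; the folds over watermarked were 1.41, 1.69 and 2.03. Taken alone, the native copy of ENO2 was -0.21 ± 0.12 log2 in double vs native (edgeR adjusted p = 0.0978 over the list alone, 0.140 over all genes). For each copy the list alone held 1 gene, so that adjustment left the p-value as it was and corrected for nothing. On that basis only, the native copy passed the threshold with DESeq2 (-0.22, adjusted p = 0.0469), without native 2 (adjusted p = 0.0458) or without double 1 (adjusted p = 0.0394). The watermarked copy of ENO2 fell by 0.23 ± 0.08 on the log2 scale in double vs watermarked (edgeR adjusted p = 0.0161 over the list alone, 0.0290 over all genes). Over the list alone it missed the threshold with total counts (-0.14, adjusted p = 0.0772), without watermarked 3 (adjusted p = 0.0732) and without double 2 (adjusted p = 0.0591). The watermarked copy lay at SGA1 in the double strain and at CAN1 in the watermarked strain, so its locus changed in this comparison too. The exact permutation test of the copy sums gave p = 0.2 for the native and p = 0.1 for the watermarked copy, with 0.1 the smallest possible. At the 3' end marker the native copy was 0.627-fold and the watermarked copy 0.740-fold of the level in its own single-set strain. At the middle markers the native copy of ENO2 was 1.07-fold and 1.09-fold, and the watermarked copy 0.916-fold and 0.957-fold.

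**Figure D1:**
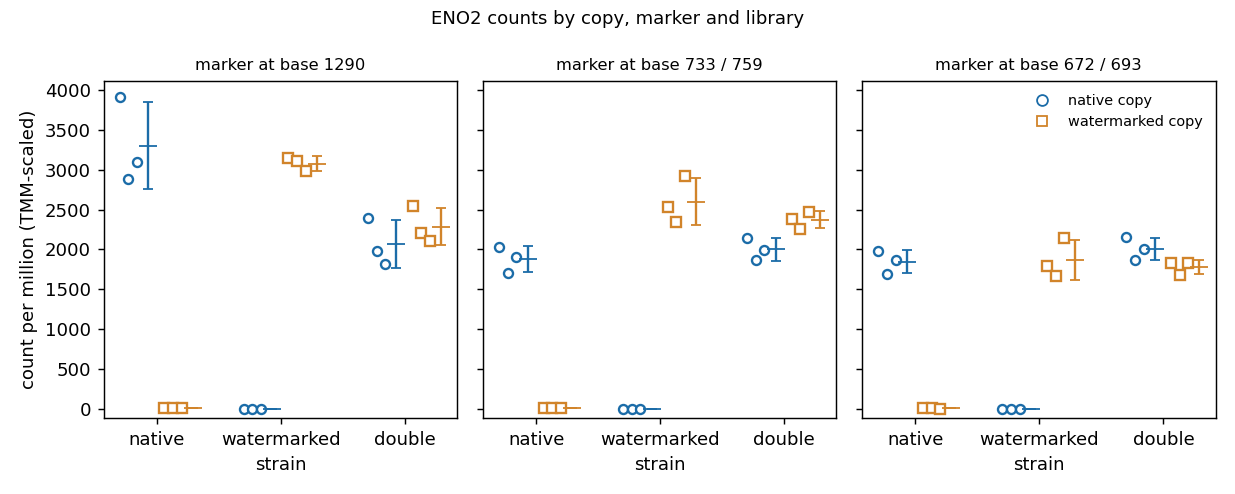
TMM-scaled CPM of ENO2 (vertical axis) by strain (horizontal axis) at each of 3 marker pairs, with circles for the native copy and squares for the watermarked copy in each of 3 libraries, and bars for the mean ± SD. The absent copy lies near 0, and both copies of the double libraries lie between 1680 and 2550 CPM at every marker.

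With watermarked in place of native glycolytic genes at the same locus, few single genes passed by edgeR. In watermarked vs native (n = 3 each), IMD2, an IMP dehydrogenase of guanine nucleotide synthesis, rose by 1.00 ± 0.14 on the log2 scale (edgeR adjusted p = 0.0407); it has near-identical relatives and is uncertain. RIB4, the lumazine synthase of riboflavin synthesis, fell by 0.50 ± 0.06, MDH2, the cytosolic malate dehydrogenase, by 0.38 ± 0.05, and YNL018C, a gene of unknown function, by 0.85 ± 0.11 (adjusted p = 0.0219 each). These 4 of 5369 genes passed, 1 of them, IMD2, changed at least 2-fold, and 842 genes had an unadjusted p under 0.05, where 268 are expected by chance. In 29.4% of genes the 2 groups did not overlap, where 10% are expected, so the low count does not show that few genes differed. Both excesses can also come from a difference between libraries that many genes share. The 3' end index was 0.03 to 0.67 in native and -0.15 to 0.01 in watermarked libraries. DESeq2 called 116 genes, 20 higher and 96 lower, with 2 of the 4 among them. The edgeR count was 0 with the 3' end index as a covariate, with the replicate number as a block, and without native 2, watermarked 1, 2 or 3, or double 1. It was 3 without double 2 (IMD2 no longer passing), 2 without native 3 or with the marker nearest the 3' end, 11 without double 3, and 13 without native 1 and double 3 together.

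Across the fixed lists, cytosolic ribosomal protein genes lay lower as a group in watermarked vs native, with a median log2 change of -0.16 (camera adjusted p = 1.81e-22; adjusted p = 0.931 with an estimated correlation). None of 107 passed over all genes by edgeR, and adjusted over the list alone 2 did, RPS27B and RPS21B, both lower; DESeq2 called 21 lower. The 3' end index of native 1 stood far above the others, and with that index as a covariate the median of the ribosomal protein genes was -0.08. The 7 glycolytic regulators lay higher, with a median of 0.19 (camera adjusted p = 0.00123; adjusted p = 0.931 with an estimated correlation). Of these regulators 0 passed over all genes and 4 adjusted over the list alone: RAP1, GCR2, GCR1 and REB1, transcription factors that bind or activate glycolytic promoters. Adjusted over the list alone, single members of other lists also passed: PDC5 and HXT15 higher, and TDH1, HIS3, URA3, IDP2, HIS1, URA4, ORT1, ARG7 and MDH2 lower. The other 36 tested lists were not called by camera in watermarked vs native, with adjusted p from 0.101 (cell cycle, M and M/G1) and 0.137 (trehalose and glycogen) to 0.985 (nitrogen catabolite genes). Fry called 0 lists, and camera with an estimated correlation 0.

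A second glycolytic set went with broad differences. In double vs native (n = 3 each), the pyrimidine genes URA1 and URA3, encoding dihydroorotate dehydrogenase and orotidine phosphate decarboxylase, fell by 3.51 ± 0.09 and 2.71 ± 0.12 on the log2 scale, the drug efflux pump gene PDR5 rose by 2.22 ± 0.11, and ribosomal protein and respiratory chain genes fell almost throughout. By edgeR 3209 of 5369 genes changed, 59.8%, with 1664 higher and 1545 lower; 254 changed at least 2-fold, 196 higher and 58 lower. Changes are relative to the TMM scale. Total counts moved the median of all genes by 0.13 and the share of higher calls from 51.9% to 70.6%. Of the 12 largest changes, URA1 (adjusted p = 6.37e-09) and URA3 were lower and 10 were higher. The cell wall mannoprotein gene TIP1 rose by 2.55 ± 0.12 and the secreted glycoprotein gene YGP1 by 3.37 ± 0.45. CIS1 rose by 4.01 ± 0.21, the basic amino acid permease gene ALP1 by 2.37 ± 0.20, FMP45 by 2.09 ± 0.24, and the stationary phase gene SPG4 by 3.10 ± 0.56. The old yellow enzyme gene OYE3 rose by 3.24 ± 0.63, HBN1 by 2.38 ± 0.40, and HSP33, which has near-identical relatives, by 2.30 ± 0.37.

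In the pyrimidine list, 8 of 11 genes were lower and 1, URA10, higher in double vs native, over all genes and adjusted over the list alone (camera adjusted p = 0.00327; adjusted p = 0.433 with an estimated correlation). URA4, the dihydroorotase gene, fell by 1.79 ± 0.07 and FUR1, of uracil salvage, by 0.88 ± 0.07; URA8 (0.11) and PPR1 (-0.07) did not pass. URA1 had 1592 ± 60.5 CPM in native and 140 ± 17.8 in double libraries, and URA3 had 1016 ± 58.5, 777 ± 93.6 and 156 ± 25.4 CPM in native, watermarked and double libraries (SD, n = 3). All strains are labelled ura3-52, and reads of KlURA3 cannot be separated from URA3 in these counts. Of the 6 tested loci and marker genes, LEU2 (-0.18 ± 0.07) and CAN1 (-0.28 ± 0.10) were also lower (list adjusted p = 0.156). The call of LEU2 was lost without native 1, double 1 or double 2 (adjusted p = 0.0794 to 0.0939), and that of CAN1 without any 1 native library, watermarked 2, double 1 or double 2 (adjusted p = 0.0509 to 0.113).

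**Figure D2:**
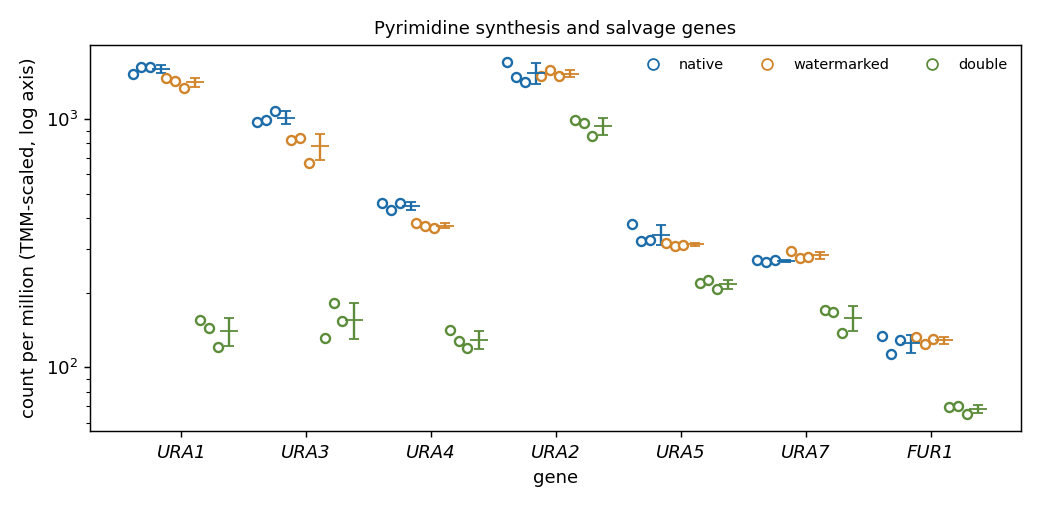
TMM-scaled CPM on a log axis (vertical) for 7 pyrimidine genes (horizontal), with a circle per library of each strain and bars for the mean ± SD (n = 3). URA1, URA3 and URA4 are lowest in the double libraries; URA1 was 140 CPM there against 1592 in native libraries.

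Genes of the translation machinery were lower in double vs native. Of 107 cytosolic ribosomal protein genes 103 fell and 1, RPS9A, rose, over all genes and adjusted over the list alone (median -0.76; camera adjusted p = 1.03e-28; adjusted p = 0.433 with an estimated correlation). RPS10B fell by 1.17 ± 0.06, RPS10A by 1.10 ± 0.06 and RPL9A by 1.43 ± 0.08; most of these genes have a near-identical partner, so single values are uncertain. Of 40 ribosome biogenesis genes 39 fell by either count (median -0.62; camera adjusted p = 3.14e-13; adjusted p = 0.433 with an estimated correlation), all but RRP12. Among them SSF1, of large subunit maturation, fell by 0.92 ± 0.07, BRX1 by 0.84 ± 0.07, and RPA34, an RNA polymerase I subunit, by 1.03 ± 0.08. The unmapped share also set the double libraries apart. Their 3' end index (-0.39 to -0.06) lay below that of every native library (0.03 to 0.67) and overlapped that of the watermarked libraries (-0.15 to 0.01). Coverage thus differed together with the strain in double vs native. With the index as covariate the ribosomal protein median was -0.65, and 2518 of all tested genes changed, against 3209 without it.

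**Figure D3:**
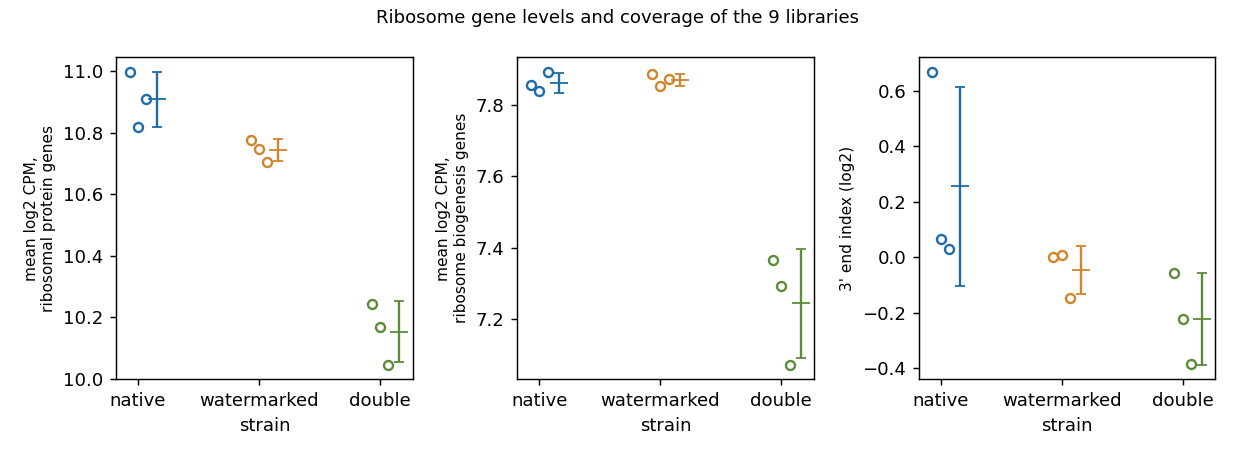
Mean log2 CPM of the ribosomal protein genes and of the ribosome biogenesis genes, and the 3' end index (log2), on the vertical axes by strain, with a circle per library and bars for the mean ± SD (n = 3). Double libraries lie at 10.0 to 10.2 for ribosomal protein genes against 10.7 to 11.0 in the 6 others, and native 1 has the highest index, 0.67.

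Nuclear genes of the respiratory chain and ATP synthase fell in 31 of 34 cases in double vs native, by either count (median -0.86; camera adjusted p = 6.78e-11; adjusted p = 0.433 with an estimated correlation). COX6 and COX4, cytochrome c oxidase subunits, fell by 1.28 ± 0.06 and 1.38 ± 0.09, and ATP3, of the ATP synthase, by 0.95 ± 0.05. The 2 members that rose were NDE1 and NDE2, external NADH dehydrogenases. In the list of heat shock and chaperone genes 23 of 28 rose, HSP60 by 1.41 ± 0.07, SSC1 by 1.06 ± 0.06 and MDJ1 by 0.98 ± 0.05, and 2, SSB1 and SSB2, which assist new chains on ribosomes, fell, by either count (camera adjusted p = 2.03e-05; adjusted p = 0.433 with an estimated correlation). Of 24 general stress genes 16 rose and 0 fell, by either count (camera adjusted p = 0.00122; adjusted p = 0.555 with an estimated correlation). They included XBP1, a transcriptional repressor (1.58 ± 0.11), MOH1 (2.00 ± 0.19) and HSP12 (1.38 ± 0.15). Cell wall integrity genes rose in 13 of 20 cases and fell in 2, by either count (camera adjusted p = 0.00789; adjusted p = 0.607 with an estimated correlation), among them YPS3 (1.28 ± 0.09), PST1 (0.79 ± 0.07) and the glucan synthase gene FKS2, also called GSC2 (1.78 ± 0.16). The 2 that fell were GAS1 and MLP1, a name that matched a nuclear pore protein gene.

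Carbon metabolism shifted in several lists in double vs native. Glycerol genes rose in 10 of 11 cases, and in 11 adjusted over the list alone (camera adjusted p = 0.000858; adjusted p = 0.433 with an estimated correlation), with GPD1 and GPD2, glycerol-3-phosphate dehydrogenases, at 0.77 ± 0.09 and 0.65 ± 0.07 and the phosphatase gene GPP2 at 0.84 ± 0.06. In gluconeogenesis and alternative carbon use 14 of 21 genes rose, 15 adjusted over the list alone, and MDH2 fell by 1.85 ± 0.05 (camera adjusted p = 0.0107; adjusted p = 0.662 with an estimated correlation); IDP2 rose by 1.22 ± 0.06 and POX1, of fatty acid oxidation, by 1.66 ± 0.14. In ethanol and acetate metabolism 7 of 12 genes rose by either count (camera adjusted p = 0.0305; adjusted p = 0.433 with an estimated correlation), led by ALD4 (1.08 ± 0.12), ADH6 (0.66 ± 0.09) and BDH2 (0.95 ± 0.16). Of 21 hexose transport and sensing genes 10 rose, HXT5 by 1.66 ± 0.15 and the repressor genes MIG3 and MIG2 by 1.10 ± 0.10 and 0.45 ± 0.05. The 2 that fell, by either count, were STD1 and HXT6 (camera adjusted p = 0.0394; adjusted p = 0.433 with an estimated correlation). The call of the hexose list was also lost with total counts (adjusted p = 0.120), the 3' end covariate (adjusted p = 0.121) or the length trend removed (adjusted p = 0.0566), and without native 1 (adjusted p = 0.0606), native 3 (adjusted p = 0.0518) or native 1 and double 3 together (adjusted p = 0.0810). That of ethanol and acetate genes was lost without double 1 (adjusted p = 0.0683). The deleted paralogs were higher in 7 of 8 tested cases by either count (camera adjusted p = 0.00327, and 0.433 with an estimated correlation), all but PDC6, at the low levels given above. These genes are labelled as deleted, and reads of relocated relatives can be counted for them. The call therefore does not show a change in carbon metabolism.

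Further lists moved in double vs native. Thiamine genes rose in 11 of 19 cases, THI4 by 1.70 ± 0.15 and THI7, a transporter gene, by 0.70 ± 0.05. THI80 (-0.58 ± 0.06) and THI3 fell (camera adjusted p = 0.0291; adjusted p = 0.433 with an estimated correlation). Fatty acid and phospholipid genes fell in 11 of 15 cases, with the elongases ELO2 and ELO3 down by 0.82 ± 0.06 and 0.71 ± 0.06 and the acyl-CoA synthetase FAA4 by 0.56 ± 0.05 (camera adjusted p = 0.00373; adjusted p = 0.433 with an estimated correlation). Sulfur and methionine genes fell in 12 of 25 cases, MET16 by 0.51 ± 0.06, MET32 by 0.47 ± 0.06 and CYS4 by 0.41 ± 0.06. STR3, MUP3 and CYS3 rose (camera adjusted p = 0.0429; adjusted p = 0.662 with an estimated correlation). The call of the thiamine list was also lost with total counts (adjusted p = 0.0505), and that of the sulfur list with the 3' end covariate (adjusted p = 0.106) and without native 3 (adjusted p = 0.0635), double 3 (adjusted p = 0.177) or native 1 and double 3 together (adjusted p = 0.168). In these 3 lists the counts adjusted over the list alone were equal to those over all genes. Of the 15 lists moved, 9 were higher and 6 lower; 0 were called with an estimated correlation and 29 by fry, which tests whether genes move without comparing them with other genes.

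The other tested lists were not called by camera in double vs native, which compares a list with all other genes. This does not show that their genes stayed unchanged. Fry called some of them, such as nitrogen catabolite (adjusted p = 0.00843) and sporulation genes (adjusted p = 0.000233), and not others, such as the TCA cycle (adjusted p = 0.315). Adjusted p-values of lists given next are those of camera. In the nitrogen catabolite list (adjusted p = 0.0926) 14 of 26 genes rose, among them PUT1 (1.92 ± 0.14) and CAR2 (1.57 ± 0.09) of proline and arginine breakdown, and GLN1 and MEP1 fell. In the pentose phosphate pathway (adjusted p = 0.712) RKI1 fell by 1.52 ± 0.10 with TKL1 and SOL3, while GND2, ZWF1, RPE1, NQM1 and TKL2 rose. In the TCA cycle (adjusted p = 0.954) 6 genes rose, IDH2 by 0.67 ± 0.07 and ACO1 by 0.69 ± 0.08, and CIT1 (-0.64 ± 0.07), ACO2, SDH2, SDH3 and KGD2 fell. Trehalose and glycogen genes (adjusted p = 0.137) rose in 12 of 20 cases, with UGP1, GLG2 and GAC1 lower. G1/S and histone genes (adjusted p = 0.0834) fell in 8 of 15 cases, CLB6 by 0.88 ± 0.10 and SWI4 by 0.44 ± 0.05, and HHT1 rose. M and M/G1 genes (adjusted p = 0.158) fell in 5 of 15: CLB1, CLB2, CDC5, SWI5 and ASH1. TYE7 rose by 0.38 ± 0.15 among the glycolytic regulators (adjusted p = 0.848), but its call was lost without double 3 (0.14, adjusted p = 0.109), without native 1 or 2, and without any 1 of the watermarked libraries. Adjusted over the list alone, 0 of the regulators passed.

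The other amino acid lists and those of ergosterol, phosphate, iron, zinc, oxidative stress and ER stress were also not called by camera in double vs native. Branched-chain synthesis (adjusted p = 0.138) had 6 of 11 genes higher, ILV6 by 0.84 ± 0.07. Arginine and lysine synthesis (adjusted p = 0.460) had ARG1, ARG3, ARG5,6, CPA1 and CPA2 higher and 8 lower, such as LYS1 at -0.85 ± 0.08. Histidine synthesis (adjusted p = 0.573) had HIS4 and HIS5 higher and HIS1 lower. For ergosterol the adjusted p was 0.848 (5 of 24 higher, namely ERG4, ERG1, ERG10, ERG12 and ERG27, and ERG20, ERG7, ERG2, ERG13 and HMG1 lower). The phosphate regulon (adjusted p = 0.204) had 6 of 13 genes higher and VTC2 lower. The iron regulon (adjusted p = 0.697) had ARN1, ISU1, FRE6 and FIT1 higher and ISU2, ATX1, SMF3 and FRE2 lower, and the zinc regulon (adjusted p = 0.672) had ZRT1 and ZRT3 higher and ZRT2, MCD4, IZH1 and IZH2 lower. Oxidative stress (adjusted p = 0.293) had 8 of 18 genes higher, OYE2 by 0.99 ± 0.12, and GPX2, TSA1 and TRR1 lower. ER stress (adjusted p = 0.205) had ERV2 higher and 6 of 16 genes lower, such as MPD1 at -0.72 ± 0.08.

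Among mating type lists in double vs native, STE2, the alpha-factor receptor gene, fell by 0.77 ± 0.07 with STE6 (MATa-specific, adjusted p = 0.293), and STE3 and SAG1 rose (MATalpha-specific, adjusted p = 0.204). For haploid and mating genes the adjusted p was 0.966, with FIG2 and FUS1 higher and FAR1, STE4 and STE5 lower. The call of STE6 was lost without native 2, native 3 or double 2 (adjusted p = 0.0682 to 0.124). Sporulation genes (adjusted p = 0.0926) were higher in 9 of 14 cases with SPS4 and SPO13 lower. Galactose and maltose genes (adjusted p = 0.712) had GAL3 (1.43 ± 0.11) and MAL11 higher and GAL80 and MAL31 lower, and subtelomeric genes (adjusted p = 0.382) had 8 of 15 higher and TIR3, PAU1, COS8 and COS12 lower. Of 8 mitochondrially encoded genes 4 were in the files and 0 had counts enough to be tested. Median, mean and test differed in sign for the glycolytic regulators and the iron and zinc regulons in double vs native. They did so in watermarked vs native for deleted paralogs, pentose phosphate, ribosome biogenesis and phosphate genes, and in double vs watermarked for pentose phosphate, TCA cycle, iron, and haploid and mating genes.

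**Figure D4:**
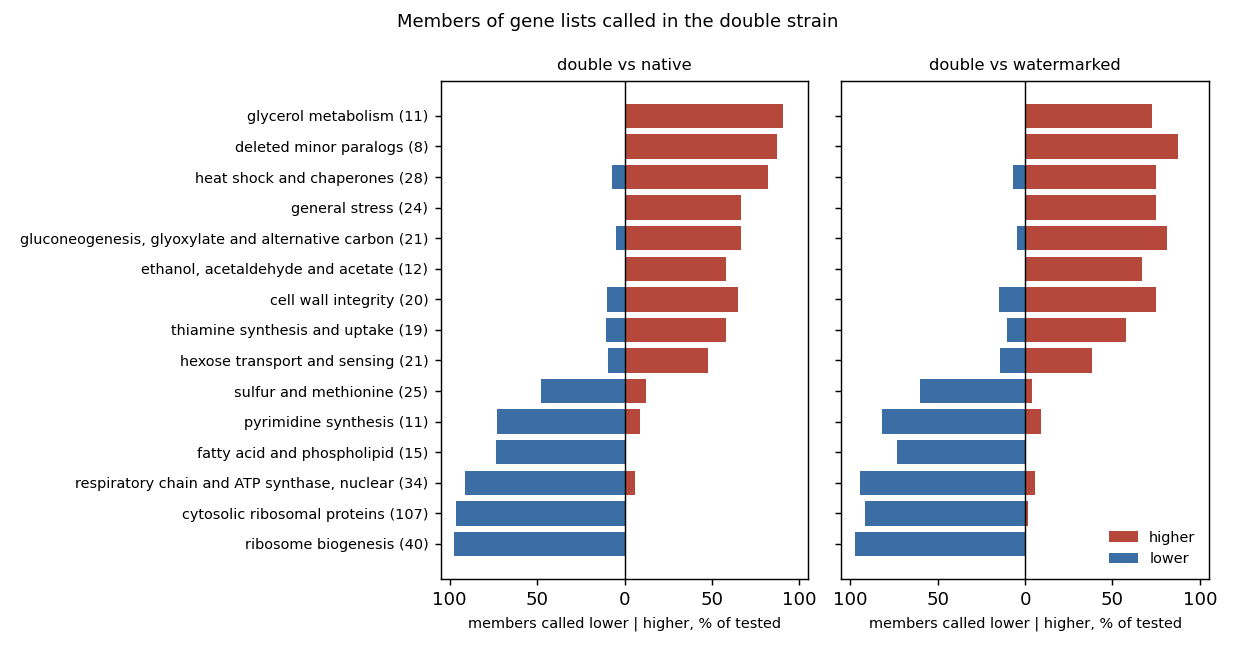
Share of the tested members of each list called higher (bars to the right) or lower (bars to the left) in the double strain, in percent of tested members (horizontal axis; number tested in parentheses), for the 15 lists moved in double vs native. Of 107 ribosomal protein genes 103 were lower in double vs native and 98 in double vs watermarked.

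The comparison of both sets with the watermarked set alone also gave broad differences. In double vs watermarked (n = 3 each), URA1 fell by 3.33 ± 0.09 on the log2 scale (edgeR adjusted p = 1.15e-08), and URA3 (-2.32 ± 0.12) and URA4 (-1.53 ± 0.07) fell with it. SNZ1 and SNO1, a gene pair of vitamin B6 synthesis, rose by 2.68 ± 0.16 and 2.64 ± 0.11. By edgeR 3227 of 5369 genes changed, 60.1%, with 1601 higher and 1626 lower; with total counts 63.6% of the calls were higher against 49.6%. At least 2-fold changes numbered 258, with 219 higher and 39 lower. The other largest changes were all higher: CIS1 (4.15 ± 0.21), SPG4 (4.06 ± 0.60), OYE3 (3.23 ± 0.62), YGP1 (3.19 ± 0.44), NQM1, a transaldolase paralog (2.60 ± 0.37), HBN1 (2.44 ± 0.39), TIP1 (2.43 ± 0.12), YPT53, a Rab GTPase (2.43 ± 0.25), and FMP45 (2.36 ± 0.24). These libraries are the double libraries of the comparison with native ones, so both sets of values share their chance deviations.

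In double vs watermarked, 98 of 107 ribosomal protein genes fell, 100 adjusted over the list alone, and RPS9A and RPL15B rose (median -0.59; camera adjusted p = 8.99e-22; adjusted p = 0.491 with an estimated correlation). RPL9A fell by 1.29 ± 0.08, and of 40 ribosome biogenesis genes 39 fell by either count, SSF1 by 0.98 ± 0.07 and UTP4 by 0.88 ± 0.07 (camera adjusted p = 5.33e-13; adjusted p = 0.491 with an estimated correlation). Respiratory chain genes fell in 32 of 34 cases by either count, COX6 by 1.20 ± 0.06 and ATP2 by 0.95 ± 0.06, and NDE1 and NDE2 rose (camera adjusted p = 3.03e-10; adjusted p = 0.491 with an estimated correlation). Of 28 heat shock and chaperone genes 21 rose, 22 adjusted over the list alone, with HSP60 at 1.33 ± 0.07 and HSP10 at 1.37 ± 0.07, and SSB1 and SSB2 fell (camera adjusted p = 1.45e-05; adjusted p = 0.491 with an estimated correlation). General stress genes rose in 18 of 24 cases by either count, XBP1 by 1.49 ± 0.11 (camera adjusted p = 0.000195; adjusted p = 0.542 with an estimated correlation). Cell wall genes rose in 15 of 20 by either count, YPS3 by 1.52 ± 0.09, and GAS1, PIR1 and MLP1 fell (camera adjusted p = 0.00238; adjusted p = 0.559 with an estimated correlation). Pyrimidine genes fell in 9 of 11 by either count and URA10 rose (camera adjusted p = 0.00238; adjusted p = 0.491 with an estimated correlation).

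Gluconeogenesis and alternative carbon genes rose in 17 of 21 cases in double vs watermarked, 18 adjusted over the list alone, IDP2 by 1.53 ± 0.06, while MDH2 fell by 1.47 ± 0.05 (camera adjusted p = 0.00252; adjusted p = 0.559 with an estimated correlation). Glycerol genes rose in 8 of 11 cases, 9 adjusted over the list alone, GPP2 by 0.88 ± 0.06 (camera adjusted p = 0.00252; adjusted p = 0.491 with an estimated correlation). Fatty acid genes fell in 11 of 15 by either count, FAA4 by 0.74 ± 0.05 (camera adjusted p = 0.00252; adjusted p = 0.491 with an estimated correlation). Deleted paralogs were higher in 7 of 8 by either count (camera adjusted p = 0.00252, and 0.491 with an estimated correlation), where reads of relocated relatives can again be counted for them. In ethanol and acetate metabolism 8 of 12 rose by either count, ALD4 by 1.13 ± 0.12 (camera adjusted p = 0.0126; adjusted p = 0.491 with an estimated correlation). Sulfur genes fell in 15 of 25 by either count, CYS4 by 0.44 ± 0.06, and STR3 rose (camera adjusted p = 0.0217; adjusted p = 0.559 with an estimated correlation). Thiamine genes rose in 11 of 19 by either count, THI4 by 2.04 ± 0.15, and THI80 and THI3 fell (camera adjusted p = 0.0281; adjusted p = 0.491 with an estimated correlation). M and M/G1 genes fell in 8 of 15 by either count, the cyclin genes CLB2 and CLB1 by 0.70 ± 0.09 and 0.68 ± 0.11 and the kinase gene CDC5 by 0.32 ± 0.05 (camera adjusted p = 0.0334; adjusted p = 0.559 with an estimated correlation). The call of M and M/G1 genes was also lost with the length trend removed (adjusted p = 0.0641) and without watermarked 3 (adjusted p = 0.0526), double 1 (adjusted p = 0.124) or double 2 (adjusted p = 0.0722), and that of sulfur genes without double 3 (adjusted p = 0.127) or native 1 and double 3 together (adjusted p = 0.165). The other lists, hexose transport among them (adjusted p = 0.181), were not called by camera, with adjusted p from 0.0697 (G1/S and histone genes) to 0.996 (TCA cycle). In all 15 lists moved, 8 higher and 7 lower; 0 were called with an estimated correlation and 30 by fry.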

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

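Tests of gene length, paired genes, scaling, ENO2 coverage and the splits of the libraries were fixed before their results were seen; the other tests in this part, and the comparison of the double libraries with the 6 single-set libraries, were chosen after the result was seen.

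The unmapped share, which no comparison of genes uses, was 19.2% in the double libraries, above that of all 6 single-set libraries (two-sided exact permutation p = 0.0119, the smallest value 3 against 6 libraries allow).

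Ribosomal protein genes lay lower in the double than in the native libraries. With the trend over gene length removed, their median log2 change was -0.75, and over the 17 genes without a paired copy it was -0.74, all 17 lower (-1.10 to -0.33). The scaling that brought the median closest to 0, total counts, left it at -0.63. These values argue against gene length, shared reads of paired genes and scaling as the whole cause. All 3 double libraries lay below the 6 others, but the labels name no culture or library preparation that crosses the strains. A difference between strains therefore cannot be told apart from one between cultures or preparations.

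URA1, URA3 and URA4 were lower in double vs native, with a median of -2.71. Reads of KlURA3 counted for URA3 do not account for URA1 and URA4, of which the less lowered, URA4, changed by -1.79; for URA3 itself (-2.71) this stays open, because KlURA3 reads cannot be separated. Whether the broad difference of the double libraries is the whole cause also stays open, because URA1 and URA3 were picked for their large changes. The median of these genes minus that of the other 9 pyrimidine genes was -2.23, but URA10, which like the 3 is a target of the activator Ppr1, rose by 0.55, and with it in the group the difference was -1.68. The double label lists no KlURA3, so a different uracil supply or marker set of the double strain is a candidate explanation, and no library of that strain with KlURA3 was there to test it.

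The ENO2 fold between double and native libraries was lower at the 3' end marker than at the most upstream one by a log2 difference of -0.63. The same difference over 180 other genes had a median of -0.49 and a middle 95% from -1.20 to 0.31, so coverage along transcripts that differed between libraries may account for it; without native 1 ENO2 stayed at -0.56 while the median of the other genes moved to -0.27 and their middle 95% to -0.70 to 0.22. Counting that treats the watermarked sequence differently cannot be the whole cause, since the native copy alone, the same sequence in both strains, differed by -0.77 between its first and second marker. A contribution stays open. The log2 ratio of watermarked to native strain was 0.46 ± 0.12 (SE) at the first middle pair, against -0.09 ± 0.14 at the 3' end and 0.01 ± 0.13 at the second middle pair. In the watermarked copy that difference was -0.31 against the watermarked strain; a changed transcript end stays open, because both copies show it and coverage gives the same sign.

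For the counts of genes, the splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. In watermarked vs native, 1 split of 10 gave as many genes as the real 4 (highest other 0), and 1 gave as many at 2-fold as the real 1 (highest other 0). In double vs native the numbers were 1 split of 10 with 3209 genes (highest other 0) and 1 with 254 at 2-fold (highest other 0). In double vs watermarked they were 1 of 10 with 3227 genes (highest other 0) and 1 with 258 at 2-fold (highest other 0). For the gene lists moved, 7 of 10 splits gave as many as the real 2 in watermarked vs native (highest other 9), 5 as many as the real 15 in double vs native (highest other 17), and 3 as many as the real 15 in double vs watermarked (highest other 19). Camera with a preset correlation thus also called lists on splits that mix the strains, where 0 genes were called. Whether a structure of the samples other than the strain lies behind this was not tested.

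The double libraries against all 6 others make 84 splits. Only the real split, 1 of 84, the smallest share possible, reached its 3322 genes (highest other 3) and 247 genes at 2-fold (highest other 2). The grouping was chosen after the result was seen. Every other split puts double and single-set libraries in 1 group, which widens the spread within it. The share therefore does not exclude chance, and it cannot tell the strain from its culture or preparation. For gene lists 30 of 84 splits moved as many as the real 14 (highest other 19), so chance cannot be excluded for the number of lists.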

How the results depend on the processing

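The settings used and most alternatives were fixed before the data were examined; the marker nearest the 3' end, the gene length and GC trends, the 3' end covariate and leaving out native 1 with double 3 were chosen after seeing the data. In double vs native, 3013 of 3057 alternatives for 133 named genes kept direction and threshold, 43 lost the threshold and 1 reversed. In double vs watermarked 3117 of 3147 did, 30 lost it and 0 reversed. Most named genes were chosen for large changes or small p-values in these same libraries. These shares therefore follow in part from that choice and do not show how other called genes would fare. Genes changed stayed within 1.5 times the main count, from 2518 to 3403 in double vs native and from 3121 to 3576 in double vs watermarked. With each library left out they ran from 2895 to 3211 and 2811 to 3428, and at 2-fold from 240 to 281 and 247 to 265. All 4 genes of watermarked vs native lost the threshold in some setting: 35 of 90 alternatives. Where a left-out library ended the call, the values were -0.54 to -0.45 for RIB4, -0.41 to -0.37 for MDH2, -0.93 to -0.77 for YNL018C and 0.92 to 1.05 for IMD2, near those with all libraries.

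Watermarked vs native depended most on the processing; the cause was not tested. Its genes changed were 0 with the 3' end covariate, 2 with the marker nearest the 3' end, 13 without native 1 and double 3, 116 with DESeq2, and 0 to 11 with each library left out (0 without native 2, watermarked 1, 2 or 3 or double 1; 2 without native 3; 11 without double 3). At 2-fold there were 0 with RLE factors, the marker nearest the 3' end, the length trend removed, the 3' end covariate or DESeq2, and 0 to 1 with each library left out (1 without native 1 or native 3); edgeR had 842 genes with an unadjusted p under 0.05. Its lists moved were 6 without native 1 and double 3, 5 with the length trend removed, 0 with an estimated correlation, 0 by fry, and 2 to 4 with each library left out (4 without watermarked 1 or double 3). Double vs native had 0 lists with an estimated correlation, 29 by fry and 13 to 16 with each library left out, and double vs watermarked 0, 30 and 15.

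ENO2 in watermarked vs native reversed with the marker nearest the 3' end, at -0.10 (adjusted p = 0.689). The adjusted p ran from 0.298 to 0.820 over settings other than leaving out each library in turn. Leaving out each library gave 0.03 to 0.20 (adjusted p = 0.515 to 0.896). Double vs native gave 0.76 to 0.93 and double vs watermarked 0.67 to 0.78 with libraries left out, and 0.41 (3' end marker) to 1.01 (3' end covariate) and 0.44 (GC trend removed) to 0.81 (total counts) over other settings. Each copy was judged here by p adjusted over the list alone, which held 1 gene, so nothing was corrected for. On that basis the native copy passed with DESeq2 (-0.22; adjusted p = 0.0469, range 0.0469 to 0.462). The native copy ran from -0.29 to -0.11 with each library left out, past the threshold without native 2 or double 1. The watermarked copy missed it with total counts (-0.14; adjusted p = 0.0772, range 0.00147 to 0.0772) and ran from -0.27 to -0.18, missing it without watermarked 3 or double 2. The ratio of copies in the double libraries turned to -0.021 when corrected for the single-copy strains, which subtracts the ratio between them, and ran from 0.06 to 0.12. CIT2 in double vs native was 0.041 with total counts, against -0.089. The absent copy's share ran from 0.132 to 0.153% and 0.0471 to 0.0618%.

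With the replicate block, watermarked vs native had 0 genes, 0 at 2-fold and 3 lists, and in double vs watermarked the calls of SAG1 and GAL80 were lost; the block changed no other call among named genes, counts and ENO2 results. Deviations of same-numbered libraries correlated from -0.11 to 0.16, and 4 of 9 matched best with their own number, so the numbers were not taken as pairs.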

Other observations

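All tests in this part were chosen after the result was seen, and the gene lists it uses were written then. With an estimated correlation none of these lists passed by camera, adjusted over 9 tests. Fisher's exact test treats the genes of a list as independent and does not measure the spread between libraries. Of all 5369 tested genes, 1664 were called higher in double vs native and 1601 in double vs watermarked.

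Mitochondrial ribosome and import genes, outside the fixed lists, rose in the double strain. Of 70 genes of the mitochondrial ribosome, 69 rose and 0 fell in double vs native (median 0.65; Fisher's exact test, adjusted p = 6.49e-34 over 9 tests; camera adjusted p = 0.126 with an estimated correlation), and 69 rose in double vs watermarked (median 0.71; adjusted p = 8.69e-35; adjusted p = 0.126 with an estimated correlation). MRPL4 rose by 1.28 ± 0.07 and MRPL11 by 0.90 ± 0.05 in double vs native (SE, n = 3 each). Of 21 genes of mitochondrial protein import and proteases 19 rose and 1 fell in each of these comparisons (adjusted p = 4.76e-08 and 3.13e-08; camera adjusted p = 0.0742 in both with an estimated correlation), such as AFG3 (0.94 ± 0.06), PIM1 (0.80 ± 0.05) and TIM44 (0.55 ± 0.05). The cytosolic ribosome and respiratory chain genes fell in the same libraries.

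Genes that the drug-resistance regulators Pdr1 and Pdr3 activate rose in 9 of 12 cases with 0 lower in double vs native (median 0.78; Fisher's exact test, adjusted p = 0.00389 over 9 tests; camera adjusted p = 0.126 with an estimated correlation). In double vs watermarked 8 rose and 1 fell (median 0.59; adjusted p = 0.0136; adjusted p = 0.132 with an estimated correlation). PDR5 and CIS1, members of this list, had been seen among the largest changes before the list was written. Others were PDR15 (1.63 ± 0.17), ICT1 (1.22 ± 0.10), PDR3 itself (1.17 ± 0.07) and SNQ2 (1.05 ± 0.08).

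A retrograde response to lost mitochondrial function was considered for the mitochondrial genes. It would raise CIT2 and DLD3. The higher of both was CIT2, at -0.089 in double vs native, and DLD3 fell by 0.35 ± 0.07. For CIT2 and DLD3 these values argue against it. No other genes were tested for this response. In the TCA cycle list 6 genes rose, ACO1 and IDH2 among them, and 5 fell, CIT1 among them. The response as a whole therefore stays open. Whether mitochondrial DNA was lost stays open, because the 4 mitochondrially encoded genes in the files held at most 6 counts together in any library, native ones included, and polyA selection leaves few of their reads.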
